A study of Mus musculus with 8 samples.

How the data were processed

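Liver RNA from 40 male C57BL/6J mice was measured on 8 Affymetrix Mouse Gene 1.0 ST arrays. Per the labels, mice ate a low-fat diet (LFD, 13% of calories from fat) or a high-fat diet (HFD, 42%) and drank deionized water, either plain or with sodium arsenite at 3 mg of inorganic arsenic per litre (As). This gave the groups LFD, LFD+As, HFD and HFD+As with 10 mice each. The labels' protocols give 10 weeks of exposure, while the source label gives 90 days; the difference could not be resolved. RNA was extracted from each mouse, and equal amounts from 5 mice were pooled for each array, per the labels' protocols. Each group therefore has 2 arrays, and the spread between arrays is a spread between pools of 5 mice.

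The deposited values are log2 signals per transcript cluster (the array's unit for a gene), made with Affymetrix Expression Console 1.0 per the submitters' processing notes. The methods of background correction, normalization and summary are not given there. The array distributions are nearly but not exactly equal. Array medians lay between 7.08 and 7.18 and values between 1.38 and 14.8, so the values were used as they are, with no pseudocount. The table holds no control probe sets and no detection calls, so the planned check of RNA quality from the ends of Actb and Gapdh could not be run, and whether a dim signal lies above background is unknown. The number of arrays limits the precision, and the median standard error of a group difference was 0.127 log2 units.

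Gene names came from the platform annotation, which lists 23410 of the 35556 clusters. One gene symbol was given for 21789 clusters, several for 1621, and 12146 clusters had none. Of the clusters with 1 symbol, 21698 matched a gene in the RefSeq table of assembly GRCm38.p6, and 0 symbols changed. The cluster with the highest mean over all 8 arrays stood for its gene, which gave 19938 genes. Of the called named genes, 1, 0, 5, 3 and 2 in the pairwise comparisons had several clusters, and 0 of these had a cluster of opposite sign. The 60% with the highest means (above 6.975) were tested, 11963 genes in all. The genomic span of a gene (first to last base, introns included) was taken from the same table for 11958 of them.

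Group differences were tested with limma 3.58.1 in R 4.3.3, in one fit of 4 group means to all 8 arrays. This left 4 residual degrees of freedom, to which the moderated variances added 9.32 prior degrees of freedom; the median residual SD was 0.122. Differences are log2 fold changes with their standard error (SE), each from 2 arrays per group, and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. The comparisons were LFD+As, HFD and HFD+As each against LFD, HFD+As against HFD, HFD+As against LFD+As, and the interaction, which is the arsenite effect on HFD minus that on LFD. Averages over both waters and over both diets compared 4 arrays with 4. Because the 3 comparisons with LFD share its 2 arrays, overlaps were set beside 100 simulations of unchanged groups. Lists of the same lengths as the called ones were taken from these after the data were seen.

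Gene lists were tested with camera in limma at its preset correlation of 0.01, adjusted over 150 tests (25 lists with at least 5 measured genes in 6 comparisons). The 29 lists were cholesterol biosynthesis and SREBP2 targets, fatty acid synthesis, fatty acid oxidation and PPAR-alpha targets, lipid droplet and lipid storage, bile acid synthesis and transport, NRF2 targets and glutathione, metal and heat shock response, unfolded protein and integrated stress response, arsenic methylation and one-carbon metabolism, xenobiotic metabolism, male-biased liver genes, female-biased liver genes, circadian clock, gluconeogenesis with fasting and glucocorticoid response, amino acid catabolism and urea cycle, interferon-stimulated genes, acute phase, cell cycle, p53 targets and DNA damage, mitochondrial oxidative phosphorylation, and markers of macrophages, lymphocytes, neutrophils, stellate cells, sinusoidal endothelium, cholangiocytes, erythroid cells, adipocytes and exocrine pancreas. A median over a list is the median log2 fold change of its measured genes. Camera compares a list with all other genes, so a list can be called higher while its median is below 0 where most genes fell.

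The named genes followed a rule. For each comparison these were the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups (the overlap condition was not applied to the interaction). Where fewer than 5 passed in a direction, the genes with the smallest unadjusted p up to 5 were taken as values only. Symbols of predicted or unnamed genes were counted and not named. Each list added up to 4 passing members with the largest change or, where none passed, up to 2 with the smallest unadjusted p as values only. Mt1, Hmox1, Nqo1, As3mt, Cyp7a1, Scd1, Sqle and Cidec were taken in every comparison. Lists, comparisons, thresholds, this rule and all but 2 alternatives were fixed before the data were examined.

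The alternatives were each array left out in turn, no filter or a stricter filter at the upper 40%, the mean of all clusters of a gene, every cluster tested singly, quantile normalization, centring each array on its median, variances with a mean trend and robust estimation, array weights, the replicate number as a block, a fit to only the arrays compared, an adjusted p under 0.1, a 1.5-fold minimum with adjusted or unadjusted p, camera with an estimated correlation, and fry. The 2 alternatives chosen after seeing the data were removal of each array's trend with gene span by loess and a block with crossed numbers in LFD+As. The removal brings each array's typical deviation near 0 at every span. It therefore pushes the numbers of higher and lower genes together, whatever caused the trend. Where an array is left out, its group's remaining array is assumed to vary like the other groups. The replicate numbers share no animal, litter or day in the labels, and they were not treated as pairs.

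The steps were tested on simulated data with 200 changed genes among 11963, of which 50 each were moved by 0.5, 1, 1.5 or 2 log2 units. At 1 log2 unit, 100% were recovered for LFD+As, HFD and HFD+As against LFD and 98% for the interaction. At 0.5, the recovered share was 56%, 64%, 58% and 18% in that order. Calls of unchanged genes numbered 9 of 187, 19 of 201, 15 of 194 and 12 of 170. For the list tests, 0 of 150 were called by camera on unchanged values (13 at an unadjusted p under 0.05), and 1 list with 20 members moved by 0.3 was called in all 4 comparisons that contained the move. The simulated genes varied independently of each other. These runs therefore cannot show how camera at its preset correlation behaves where the genes of a list vary together. The moved genes were also picked at random, and the simulated arrays held no trend with gene span. The recovered shares need not hold for genes that vary more than most. Clusters with several gene symbols and genes below the filter are not analysed here, and clusters with no single gene name were only counted.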

Results

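Livers of male mice were compared after low-fat or high-fat feeding with and without arsenite in the drinking water, with RNA of 10 mice per group measured as 2 pools of 5 mice (replicate 1 and replicate 2). Signals correlated across genes at r between 0.970 and 0.994 for any pair of arrays and between 0.988 and 0.993 within a group; genes are not independent replicates. Of 11963 genes tested with limma, 8 passed an adjusted p of 0.05 for LFD+As against LFD, 55 for HFD and 1909 for HFD+As. Signals also followed the genomic span of the genes, to a different degree in each array. Across genes, the rank correlation of an array's deviations with span was 0.342 and 0.138 in LFD, 0.220 and 0.346 in LFD+As, 0.245 and -0.136 in HFD, and -0.454 and -0.293 in HFD+As (replicates 1 and 2). Every p-value of a single gene here measures the spread between pools, not between mice. Camera p-values set the genes of a list against all other genes at the preset correlation. They rest on the spread across genes and do not measure how well pools of a group repeat.

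**Figure D1:**
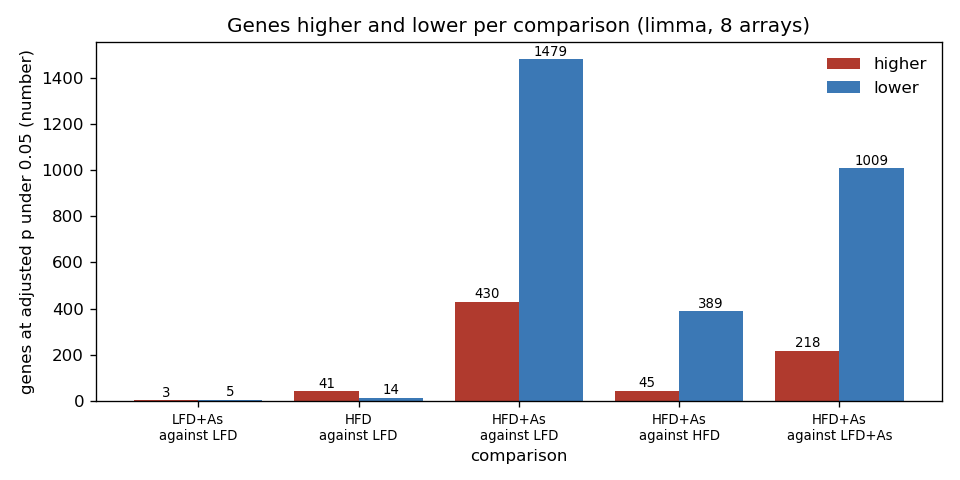
Number of genes higher (red) and lower (blue) at an adjusted p under 0.05 in each pairwise comparison (x axis), from 11963 genes and 8 arrays. HFD+As against LFD had 430 genes higher and 1479 lower, while LFD+As against LFD had 3 and 5.

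Arsenite on the low-fat diet lowered Socs2, whose product restrains growth hormone signalling. Socs2 fell by 2.04 log2 units against LFD (SE 0.19, adjusted p = 0.000546, n = 2 pools per group). Lcn2, an iron-siderophore binding protein of the acute phase, rose by 2.31 (SE 0.37, adjusted p = 0.0396), Fabp2, the intestinal-type fatty acid binding protein, by 0.98 (SE 0.14, adjusted p = 0.0256) and Creld2, a gene induced by stress of the endoplasmic reticulum, by 0.85 (SE 0.13, adjusted p = 0.0396). The interferon-induced GTPase gene Gbp11 fell by 1.08 (SE 0.16, adjusted p = 0.0256) and Phlda1, a pleckstrin homology family gene, by 1.0 (SE 0.14, adjusted p = 0.0256). Gpcpd1, which encodes a glycerophosphocholine phosphodiesterase, and the receptor gene Gpr146 were lower by 0.74 and 0.72 (adjusted p = 0.0396 for both). Of these 8 genes 3 were higher and 5 lower, while 401 genes had an unadjusted p under 0.05. Without LFD replicate 1, 0 genes were called by limma (679 at an unadjusted p under 0.05) and Socs2 stood at -2.10. The number called was 1 without LFD+As replicate 1, 26 without LFD+As replicate 2 and 15 without either HFD array. With any 1 array left out, Lcn2 lay between 1.69 and 2.92, Fabp2 between 0.84 and 1.12, Creld2 between 0.697 and 0.997 and Gbp11 between -1.28 and -0.88. Of the 8 calls, 3 held without LFD replicate 2, 1 without LFD+As replicate 1, 6 without LFD+As replicate 2 and 5 without either HFD+As array. With the span trend removed Lcn2 was not called (2.31, adjusted p = 0.149), because its SE was 0.41 instead of 0.37 and the prior degrees of freedom were 6.58 instead of 9.32, while the other 7 were.

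Of the genes that arsenite is known to act on, Mt1 and Mt2 gave large values with wide errors on the low-fat diet. The metallothionein genes Mt1 and Mt2 stood at 1.41 (adjusted p = 0.549) and 2.33 (adjusted p = 0.160), and the small heat shock protein gene Hspb1 at 0.88 (adjusted p = 0.267). Hmox1 was at 0.35, Nqo1 at 0.10 and As3mt, which encodes the arsenic methyltransferase, at 0.18. Of the genes of sterol and lipid handling, Cyp7a1 was at 0.09, Scd1 at -0.23, Sqle at 0.03 and Cidec at 0.37. Retsat, a retinol saturase gene, had 0.77 (adjusted p = 0.0898). None of these passed the test.

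As groups, acute phase genes were higher in LFD+As, with 22 of 23 measured members positive (median 0.15, mean 0.62, adjusted p = 1.27e-14). Metal and heat shock genes had 16 of 17 positive (median 0.31, adjusted p = 1.31e-12), unfolded protein and stress response genes 18 of 23 (median 0.29, adjusted p = 1.51e-11) and fatty acid oxidation and PPAR-alpha targets 23 of 26 (median 0.18, adjusted p = 3.08e-08). All 20 fatty acid synthesis genes were negative (median -0.23, adjusted p = 2.17e-08), among them Scd2 at -0.68 and Srebf1 at -0.47, and 16 of 21 interferon-stimulated genes were (median -0.30, adjusted p = 1.45e-07), with Usp18 at -0.80 and Rsad2 at -0.74. Over all genes, 1 acute phase member (Lcn2) and 1 stress response member (Creld2) were called higher, and 0 members of the other lists were called. Adjusted over the list alone, 8 acute phase, 5 metal, 5 stress response and 0 oxidation genes were higher, and 2 synthesis and 3 interferon genes lower. Each of these lists had adjusted p = 0.822 with an estimated correlation. Without LFD+As replicate 1 the synthesis median was -0.05 and the call was lost, and the acute phase and metal medians were 0.09 and 0.13. The acute phase median was 0.24 without LFD+As replicate 2, the oxidation median 0.12 without LFD replicate 2, and the interferon median -0.17 without LFD replicate 1.

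Smaller shifts in LFD+As were called for 4 further lists, with 0 members called over all genes in any of them. Male-biased liver genes had 13 of 18 positive (median 0.14, adjusted p = 0.00934), genes of gluconeogenesis and fasting 10 of 18 (median 0.11, adjusted p = 0.00711, Pck1 at 0.85) and cell cycle genes 13 of 15 (median 0.09, adjusted p = 0.00992). All 5 exocrine pancreas markers were negative (median -0.10, adjusted p = 0.0483, Cela1 at -0.32). Adjusted over the list alone, 5 fasting genes were higher and 0 genes of the other lists passed. All 4 had adjusted p = 0.822 with an estimated correlation. The male-biased, fasting and cell cycle calls were lost without LFD replicate 1 (medians 0.08, 0.16 and 0.13) and without LFD+As replicate 2 (0.05, 0.06 and 0.03), and the fasting median was -0.01 without LFD replicate 2. The pancreas call was lost without LFD replicate 2 and without LFD+As replicate 2 (-0.04 in both) and, at an unchanged median of -0.10, without either HFD array or HFD+As replicate 2. Its loss with the gene-span trend removed was at adjusted p = 0.0584.

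Acute phase, metallothionein and chemokine genes were among those higher with the high-fat diet. Saa1, which encodes the acute phase protein serum amyloid A1, rose by 4.01 (SE 0.57, adjusted p = 0.00913, n = 2 pools per group) and Lcn2 by 3.06 (SE 0.37, adjusted p = 0.00417), both genes of the acute phase. The size for Saa1 rests on LFD signals of 5.04 and 7.51 that were not shown to be above background. Mt2 and Mt1, which encode metal-binding metallothioneins, rose by 2.93 (SE 0.48, adjusted p = 0.018) and 2.47 (SE 0.39, adjusted p = 0.0167). The chemokine genes Ccl2 and Cxcl1 rose by 1.46 (SE 0.23, adjusted p = 0.0167) and 1.36 (SE 0.17, adjusted p = 0.00417), and Angptl4, a lipase inhibitor gene, by 1.13 (SE 0.13, adjusted p = 0.00417). Saa3 (1.99), the cochaperone gene Dnajc12 (1.65), the pentraxin gene Apcs (1.45), the hepatokine gene Fgl1 (1.16) and Creld2 (0.82) were also higher. Cyp26a1, whose product breaks down retinoic acid, fell by 2.28 (SE 0.26, adjusted p = 0.00417). Raet1d, a natural killer receptor ligand gene, fell by 1.63 (SE 0.22, adjusted p = 0.00624) and Etnppl, a phospholyase gene, by 1.33 (SE 0.17, adjusted p = 0.00624). Cyp2b9 (-2.22), Clec2h (-1.41), Cyp2a22 (-1.20), Gbp11 (-0.93), Akr1c19 (-0.92), Gstt3 (-0.88) and Nrep (-0.81) were lower as well. Probes of Saa, Mt, Cyp2, Cyp4a and Gst family members may bind transcripts of their close relatives.

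Of the 55 genes called in HFD, 41 were higher and 14 lower, and 15 and 6 of them changed at least 2-fold. Without LFD replicate 1, 0 genes were called by limma (1829 at an unadjusted p under 0.05, against 1232 with all arrays). The number was 11 without LFD replicate 2 and 16 without HFD replicate 2. Of the 22 named genes, 0 stayed called without LFD replicate 1, 8 without LFD replicate 2, 7 without HFD replicate 2 and 17 without HFD replicate 1. Saa1 stood at 2.77, Cyp2b9 at -1.37 and Cyp2a22 at -0.72 without LFD replicate 1, and without HFD replicate 2 Saa3 stood at 1.22 and Apcs at 0.91. Cxcl1, Cyp26a1, Etnppl and Lcn2 lost their calls only without LFD replicate 1, and with any 1 array left out they lay between 1.17 and 1.55, -2.40 and -2.17, -1.54 and -1.11, and 2.45 and 3.68. Of the 22 calls, 19 held with the span trend removed, and those of Saa3 (1.94), Apcs (1.41) and Cyp2b9 (-2.23) were lost at 0.97 to 1.01 times their changes before, with larger SE (0.40, 0.30 and 0.42, against 0.35, 0.28 and 0.40).

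**Figure D2:**
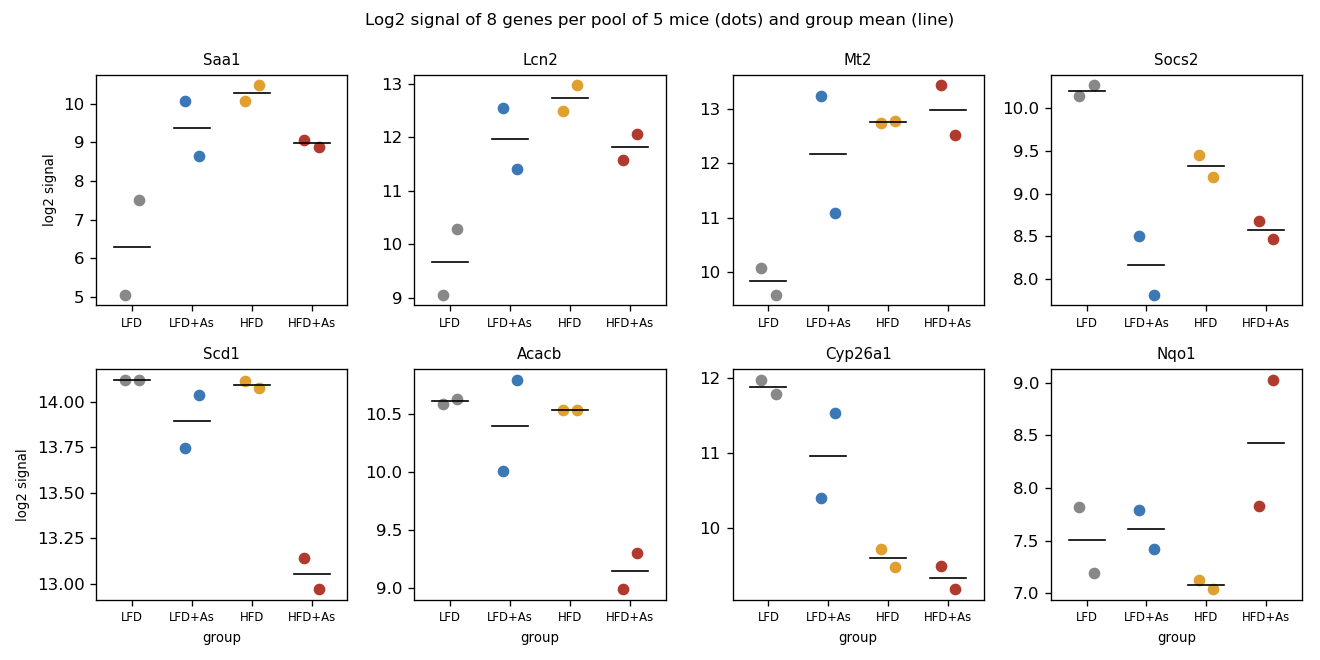
Log2 signal (y axis) of 8 genes in the 2 pools of each group (dots), with the group mean as a line. Socs2 lay at 10.1 and 10.3 in LFD and at 8.51 and 7.82 in LFD+As, and Saa1 differed between the LFD pools (5.04 and 7.51).

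All 23 acute phase genes were positive in HFD (median 0.47, adjusted p = 5.08e-19), 5 of them called over all genes and 16 adjusted over the list alone, and the list was called without any 1 array. Metal and heat shock genes had 15 of 17 positive (median 0.26, adjusted p = 3.67e-07), with 2 called and 6 adjusted over the list alone. All 23 genes of amino acid catabolism and the urea cycle were negative (median -0.17, adjusted p = 5.72e-09), with 0 called over all genes and 8 adjusted over the list alone; Prodh was at -0.55, Hal at -0.50 and Cth at -0.61. The median of that list was -0.34 without HFD replicate 1. Macrophage markers had 16 of 22 positive (median 0.22, adjusted p = 0.000413), with Marco at 0.42 and Cd68 at 0.39, 0 called and 4 adjusted over the list alone. The macrophage call was lost without HFD replicate 1 (0.21), and the median was 0.37 without HFD replicate 2. With an estimated correlation these lists had adjusted p = 0.822. Macrophage markers thus moved in the same comparison as the acute phase and chemokine genes.

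Some lists of metabolism were lower in HFD and others were not. Xenobiotic genes had 15 of 18 negative (median -0.14, adjusted p = 0.000325), with 1 called (Cyp2b9) and 3 adjusted over the list alone. Bile acid genes had 15 of 21 negative (median -0.21, adjusted p = 0.00223, Cyp27a1 at -0.38), NRF2 and glutathione genes 17 of 24 (median -0.18, adjusted p = 0.00327), and arsenic methylation and one-carbon genes 15 of 20 (median -0.11, adjusted p = 0.0102). The 8 female-biased genes were all negative (median -0.18, adjusted p = 0.0123, Cyp2b9 called), as were the 5 pancreas markers (median -0.16, adjusted p = 0.0245, Ctrb1 at -0.41). Stress response genes had 16 of 23 positive (median 0.20, adjusted p = 0.00221, Creld2 called), fasting genes 11 of 18 (median 0.14, adjusted p = 0.0474, Mt1 and Angptl4 called) and oxidative phosphorylation genes 25 of 32 (median 0.10, adjusted p = 0.013, Cox7a2 at 0.37). Fatty acid oxidation genes, with 18 of 26 positive (median 0.13, adjusted p = 0.152), and fatty acid synthesis genes, with 10 of 20 (median 0.0084, adjusted p = 0.372), were not called. Adjusted over the list alone, 3 stress response and 5 fasting genes were higher, 1 NRF2 gene was higher, and 1 one-carbon, 1 female-biased and 1 pancreas gene were lower. For oxidative phosphorylation the adjusted p was 0.833 with an estimated correlation, and for the other lists it was 0.822.

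Single arrays decided several of these HFD lists. The stress response (0.21), female-biased (-0.03) and fasting (0.19) calls were lost without LFD replicate 1, and the bile acid, NRF2, xenobiotic and one-carbon medians were -0.13, -0.07, -0.06 and -0.05. Without HFD replicate 1 the calls of NRF2 (-0.15), stress response (0.06), female-biased (-0.17), fasting (0.08) and pancreas genes (-0.10) were lost, and the one-carbon median was -0.20. Oxidative phosphorylation lost its call without HFD replicate 2 (0.06) and had 0.03 without LFD replicate 2 and 0.16 without LFD replicate 1. Without HFD replicate 2 the bile acid median was -0.05, the one-carbon median -0.06 and the stress response median 0.33. Without LFD replicate 2 the pancreas call was lost (-0.07), and the one-carbon, female-biased and fasting medians were -0.18, -0.42 and 0.07. The fasting call was also lost without HFD+As replicate 2 (0.14). With the gene-span trend removed, oxidative phosphorylation was no longer called (adjusted p = 0.0692).

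Genes of the fatty acid synthesis list were lower with high-fat feeding and arsenite together than in LFD. Against LFD, Acacb, which encodes acetyl-CoA carboxylase 2, fell by 1.46 (SE 0.20, adjusted p = 0.0021, n = 2 pools per group), the acetyl-CoA synthetase gene Acss2 by 1.45 (SE 0.18, adjusted p = 0.00136), and the stearoyl-CoA desaturase genes Scd2 and Scd1 by 1.34 and 1.07 (SE 0.20 and 0.13, adjusted p = 0.00312 and 0.00111). Mlxipl, the gene of the glucose-responsive factor ChREBP, fell by 1.22 (SE 0.16, adjusted p = 0.0021) and Insig1, a regulator of SREBP processing, by 0.73 (SE 0.12, adjusted p = 0.0039). Cyp26a1 (-2.54), the acetylcholine receptor gene Chrna4 (-2.50), Raet1d (-2.46), Socs2 (-1.62), the kinase gene Camk1d (-1.59) and Arid5b (-1.43) were lower too, with adjusted p from 0.000258 to 0.00292. Mt2 rose by 3.14 (SE 0.48, adjusted p = 0.00333), Hspb1 by 1.51 (SE 0.20, adjusted p = 0.00191), Fabp2 by 1.43 (SE 0.14, adjusted p = 0.000265), Angptl4 by 1.02 (SE 0.13, adjusted p = 0.00191) and Nr1i3, the gene of the xenobiotic receptor CAR, by 0.95 (SE 0.16, adjusted p = 0.00531). The small nucleolar RNA gene Snord57 rose by 1.85 (SE 0.24, adjusted p = 0.00196). The calls of all these genes, and of Abcb11, Creld2, Hal, Prodh and Stab2, held without any 1 array, 23 genes in all. Scd1 lay near the top of the array's range at 14.1 in both LFD pools.

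Other genes changed in HFD+As against LFD with calls that single arrays decided. Saa1 rose by 2.70 (SE 0.57, adjusted p = 0.00971), Mt1 by 2.36 (SE 0.39, adjusted p = 0.00429), Lcn2 by 2.15 (SE 0.37, adjusted p = 0.00518), Saa3 by 1.93, the small nucleolar RNA gene Snord118 by 1.70 and Hamp, which encodes the iron hormone hepcidin, by 1.52. The NRF2 targets Nqo1 and Hmox1 rose by 0.92 (SE 0.29, adjusted p = 0.0492) and 0.59 (SE 0.14, adjusted p = 0.0163). Cyp2b9 fell by 2.38 (SE 0.40, adjusted p = 0.00494) and the transcription factor gene Onecut1 by 1.43 (SE 0.41, adjusted p = 0.0338). Without LFD replicate 1 the calls of Saa1 (1.47), Lcn2 (1.53), Saa3 (1.85), Hamp (1.31), Nqo1 (1.23), Hmox1 (0.64) and Onecut1 (-1.62) were lost, and Cyp2b9 stood at -1.53. Without HFD+As replicate 1 those of Saa1 (2.61), Mt1 (2.07), Saa3 (1.68), Hamp (0.93), Hmox1 (0.55), Onecut1 (-0.64) and Cyp2b9 (-2.24) were lost, without HFD+As replicate 2 that of Nqo1 (0.32), and without LFD replicate 2 those of Snord118 (1.25), Nqo1 (0.61), Hmox1 (0.53) and Onecut1 (-1.24). Over 86 named genes, 31 stayed called without LFD replicate 1, 45 without LFD replicate 2, 33 without HFD+As replicate 1 and 64 without HFD+As replicate 2, and 64 did with the span trend removed. The 22 then lost, among them Nqo1 (0.99) and Onecut1 (-1.29), kept their sign, 20 with a smaller and 2 with a larger change (median 0.805 times that before). Sqle stood at -0.39 (adjusted p = 0.0507), As3mt at -0.16, Cyp7a1 at -0.03 and Cidec at 0.39.

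Of the 1909 genes called in HFD+As against LFD, 430 were higher and 1479 lower (77.5% lower), and 3690 had an unadjusted p under 0.05. The split followed genomic span: 240 genes were higher and 84 lower among the 20% of genes with the shortest spans, against 8 and 641 in the 20% with the longest. With the span trend removed, 1135 genes were called, 547 higher and 588 lower. That balance follows largely from the removal itself, which moved the all-gene median from -0.095 to 0.002, and does not tell artefact from biology. The count was 357 (212 higher, 145 lower) without LFD replicate 1, 776 (89 and 687) without LFD replicate 2 and 206 (67 and 139) without HFD+As replicate 1. At least 2-fold changes numbered 21 higher and 44 lower.

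**Figure D3:**
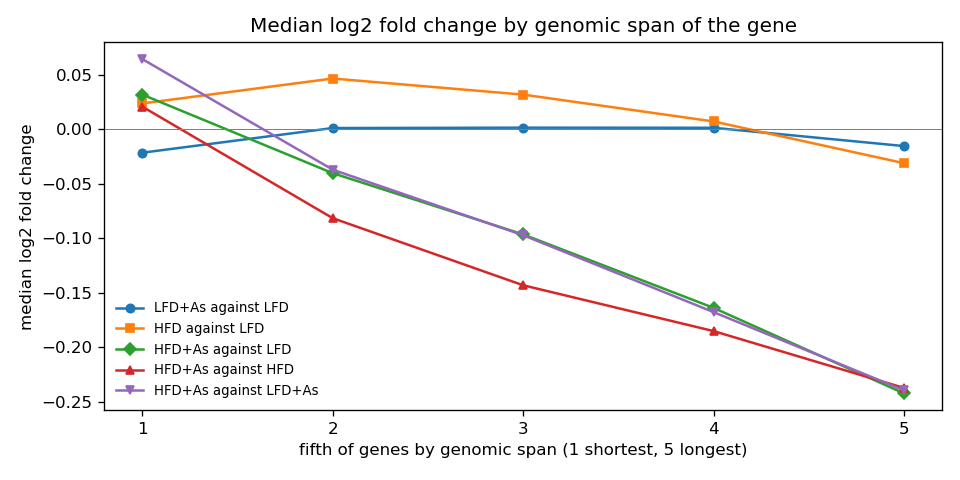
Median log2 fold change (y axis) of genes in 5 equal groups by genomic span (x axis, from the shortest to the longest), 1 line per comparison. In HFD+As against LFD the median was 0.03 in the shortest group and -0.24 in the longest.

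All 20 fatty acid synthesis genes were negative in HFD+As against LFD (median -0.82, adjusted p = 1.55e-11), 15 of them called over all genes and all 20 adjusted over the list alone. Cholesterol biosynthesis genes had 17 of 19 negative (median -0.32, adjusted p = 0.00754), with 6 called, such as Stard4 (-0.65) and Sc5d (-0.61), and 8 adjusted over the list alone. Sinusoidal endothelial markers, which stand for another cell type, had 16 of 17 negative (median -0.46, adjusted p = 0.00293), with 9 called, such as Stab2 (-0.91), Dnase1l3 (-0.90), Eng (-0.79) and Tek (-0.72), and 10 adjusted over the list alone. With an estimated correlation the synthesis list had adjusted p = 0.822, as did the cholesterol and endothelial lists. Their medians with the span trend removed were -0.76, -0.23 and -0.40, and 12, 5 and 9 of their members were called. Genes of amino acid catabolism had 22 of 23 negative (median -0.32, adjusted p = 0.00397), with 6 called, such as Hal and Prodh (-0.94 each), and 7 adjusted over the list alone. Without HFD+As replicate 1 the calls of Stard4 (-0.61), Sc5d (-0.55), Dnase1l3 (-0.92), Eng (-0.59) and Tek (-0.62) were lost, as were those of Sc5d (-0.57), Dnase1l3 (-0.82), Eng (-0.74) and Tek (-0.60) without LFD replicate 1 and that of Eng (-0.85) without LFD replicate 2. Tek stood at -0.46 with the span trend removed. The amino acid list lost its call without HFD+As replicate 1 (-0.17), and its adjusted p was 0.824 with an estimated correlation. Its median with the span trend removed was -0.13, and 4 members were called.

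Acute phase genes had 17 of 23 positive in HFD+As against LFD (median 0.22, adjusted p = 4.6e-06), with 6 called higher, and 9 higher and 1 lower adjusted over the list alone. Metal and heat shock genes had 13 of 17 positive (median 0.26, adjusted p = 6.28e-07), with 6 called, such as Hsp90aa1 (0.69), and 7 adjusted over the list alone. Oxidative phosphorylation genes had 22 of 32 positive (median 0.13, adjusted p = 9.93e-05), with Ndufb8 (0.63) among 3 called higher and Sdha (-0.55) the 1 called lower, and with 9 higher and 1 lower adjusted over the list alone. Fatty acid oxidation genes had 17 of 26 positive (median 0.08, adjusted p = 0.00221), with 4 called higher, such as Cyp4a14 (0.65), and 2 lower, Pdk4 (-1.04) and Acot2 (-0.70), and 5 and 2 adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.822. Stress response genes had 14 of 23 positive (median 0.07, adjusted p = 0.0102, and 0.824 with an estimated correlation), with 3 called higher and 1 lower over all genes and adjusted over the list alone. Their call was lost without LFD replicate 1 (0.09), without HFD+As replicate 2 (-0.0024) and with the span trend removed (adjusted p = 0.242). Without LFD replicate 1 the acute phase, oxidative phosphorylation and oxidation medians were 0.13, 0.21 and 0.13, without LFD replicate 2 the last 2 were 0.08 and 0.05, and without HFD+As replicate 2 the acute phase median was 0.11. The calls of Hsp90aa1 (0.80), Ndufb8 (0.67), Sdha (-0.57), Cyp4a14 (0.77) and Pdk4 (-1.26) were lost without HFD+As replicate 1, and those of Hsp90aa1 (0.55), Sdha (-0.57), Cyp4a14 (0.80), Pdk4 (-0.66) and Acot2 (-0.58) without LFD replicate 1. Lost without LFD replicate 2 were those of Ndufb8 (0.47), Sdha (-0.54) and Cyp4a14 (0.49), and without HFD+As replicate 2 those of Hsp90aa1 (0.58), Cyp4a14 (0.52) and Pdk4 (-0.82). All 6 of these genes stayed called with the span trend removed, when the medians were 0.21 for acute phase, 0.37 for metal and heat shock, 0.15 for oxidative phosphorylation and 0.20 for fatty acid oxidation genes.

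**Figure D4:**
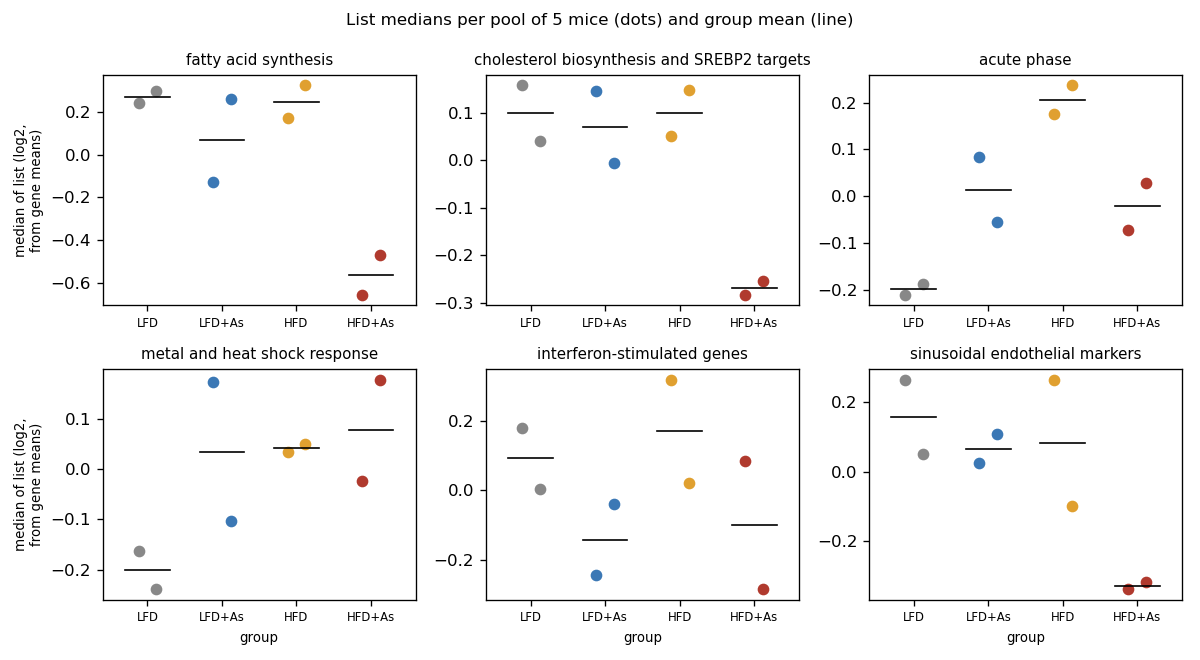
Median of 6 gene lists in each pool (dots), in log2 units from the gene means over the 8 arrays, with the group mean as a line. The median log2 fold change of HFD+As against LFD was -0.82 for fatty acid synthesis and -0.46 for sinusoidal endothelial markers.

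Within the high-fat diet, arsenite again went with lower lipid synthesis genes. Against HFD, Acacb fell by 1.39 (SE 0.20, adjusted p = 0.00645, n = 2 pools per group), the citrate lyase gene Acly by 1.27 (SE 0.22, adjusted p = 0.0164), the elongase gene Elovl5 by 1.13 (SE 0.15, adjusted p = 0.00354) and Scd1 by 1.04 (SE 0.13, adjusted p = 0.00354). Chrna4 fell by 2.31 (SE 0.23, adjusted p = 0.0016), the nuclear receptor gene Ppard by 1.5 (SE 0.20, adjusted p = 0.00354), Fabp5 by 1.32 (SE 0.17, adjusted p = 0.00354), Camk1d by 1.22 (SE 0.15, adjusted p = 0.00354) and Ccnd1, the cyclin D1 gene, by 1.09 (adjusted p = 0.00354). Nqo1, a quinone reductase gene under NRF2, rose by 1.35 (SE 0.29, adjusted p = 0.0345), the aldo-keto reductase gene Akr1c19 by 1.31 (SE 0.17, adjusted p = 0.00354), Derl3, which acts in disposal of misfolded proteins, by 1.22 (SE 0.25, adjusted p = 0.0292), Cyp4a31 by 1.19 (adjusted p = 0.0307) and Hspb1 by 0.97 (adjusted p = 0.0288). Cyp4a14 (0.95), Snord57 (0.96), Pir (0.93), Nat8 (0.91) and Etnppl (0.89) were higher, and Igfbp1 (-1.23), Mindy2 (-1.14), Orm2 (-1.11) and Sqle (-0.52) lower. Values were -0.30 for As3mt, 0.37 for Cyp7a1, 0.11 for Cidec, -0.02 for Hmox1 and -0.11 for Mt1, and none of these passed.

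Only Akr1c19, Camk1d, Ccnd1, Chrna4, Elovl5, Fabp5, Ppard and Scd1 stayed called in HFD+As against HFD without any 1 array, of 43 named genes. Without HFD+As replicate 2 the calls of Nqo1 (0.74), Derl3 (1.09), Cyp4a14 (0.83) and Cyp4a31 (0.94) were among those lost, and without HFD+As replicate 1 those of Acacb (-1.23), Acly (-1.04), Hspb1 (0.85) and Snord57 (0.40). The named calls that held were 21 without either LFD array, 37 without either LFD+As array, 12 and 34 without HFD replicates 1 and 2, and 10 and 18 without HFD+As replicates 1 and 2, and Orm2 stood at -0.64 without HFD replicate 2. Removal of the span trend left 16 of the 43 named calls, among them those of Akr1c19, Camk1d, Ccnd1, Chrna4, Elovl5, Fabp5, Ppard, Scd1, Acacb and Cyp4a14, and 27 were lost. All 27 kept their sign, 23 with a smaller and 4 with a larger change (median 0.794 times that before), and had an unadjusted p under 0.05. Among them Nqo1 stood at 1.47 (SE 0.31, against 1.35 and 0.29), Derl3 at 1.19, Cyp4a31 at 1.31, Hspb1 at 0.90, Snord57 at 0.70, Igfbp1 at -1.20, Orm2 at -1.11, Acly at -1.07, Mindy2 at -0.94 and Sqle at -0.39. The highest unadjusted p that passed went from 0.00181 to 0.000174, and 12 of the 27 lay under the former, so those calls ended with the adjustment over fewer small p-values. Of the 434 genes called, 45 were higher and 389 lower (89.6% lower), and 3140 had an unadjusted p under 0.05. In the 20% of genes with the longest spans 3 were higher and 153 lower. With the span trend removed, 43 genes were called, 23 higher and 20 lower, and with quantile normalization 104 were, 21 higher and 83 lower. The number was 135 without either LFD array, 25 without HFD replicate 1, 1121 without HFD replicate 2 and 24 (10 higher, 14 lower) without HFD+As replicate 1.

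Lists of HFD+As against HFD showed 20 of 20 fatty acid synthesis genes negative (median -0.81, adjusted p = 1.55e-13), 14 called over all genes and 19 adjusted over the list alone. Cholesterol genes had 18 of 19 negative (median -0.38, adjusted p = 0.00383), with 5 called, such as Insig1 (-0.53) and Dhcr7 (-0.50), and 9 adjusted over the list alone, and the call was lost without HFD replicate 2 (-0.35). NRF2 genes were higher as a list (14 of 24 positive, median 0.08, adjusted p = 7.42e-06), with Nqo1 and Ephx1 (0.53) called, and 5 higher and 1 lower adjusted over the list alone. Acute phase genes had 21 of 23 negative (median -0.31, adjusted p = 0.0165), with Orm2 and Itih4 (-0.59) called and 6 adjusted over the list alone. Macrophage markers had 19 of 22 negative (median -0.39, adjusted p = 0.0429), with Ctss (-0.69), Cd163 (-0.62), Adgre1 (-0.61) and Cd5l (-0.59) called and 8 adjusted over the list alone, and endothelial markers 17 of 17 (median -0.43, adjusted p = 0.00637), with 1 called (Stab2, -0.73) and 9 adjusted over the list alone. With an estimated correlation the adjusted p was 0.833 for macrophage and 0.824 for endothelial markers, and 0.822 for the other lists. The acute phase call was lost without HFD replicate 2 (-0.22) and HFD+As replicate 1 (-0.21), and the NRF2 median was 0.14 without HFD replicate 1 and 0.04 without HFD+As replicate 2. The macrophage call was lost without HFD replicate 1 (-0.26), without HFD+As replicate 2 (-0.23) and without either LFD array (-0.39), and the endothelial call without HFD replicate 1 (-0.15). Calls of 9 of these members were also lost without HFD replicate 1, where Insig1 stood at -0.51, Dhcr7 at -0.55, Ephx1 at 0.55, Itih4 at -0.53, Ctss at -0.51, Cd163 at -0.50, Adgre1 at -0.45, Cd5l at -0.57 and Stab2 at -0.50, and each of the 9 was lost without at least 1 HFD+As array too. Ephx1 lost its call whichever array was left out and stood at 0.35 without HFD+As replicate 2. After removal of the span trend 4 synthesis genes were called lower and 1 NRF2 gene higher, and 0 cholesterol, acute phase, macrophage and endothelial genes were called by limma, while these 6 lists stayed called (medians -0.63, 0.20, -0.30, -0.20, -0.25 and -0.24).

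In 4 lists of this comparison the median was small beside the test, because most genes fell (all-gene median -0.13). Fatty acid oxidation genes were called higher (adjusted p = 0.0283) at a median of -0.02 and a mean of 0.03, with 11 of 26 positive and 3 called, Cyp4a31, Cyp4a14 and Cyp4a10 (0.77), also adjusted over the list alone. Xenobiotic genes (median 0.01, 10 of 18 positive, adjusted p = 0.013) had 1 called, Nr1i3 at 0.80, as adjusted over the list alone. Oxidative phosphorylation genes (median 0.01, 18 of 32 positive, adjusted p = 0.00766) had 1 called lower, Sdha at -0.47, and 0 adjusted over the list alone. Lymphocyte markers (median 0.04, 6 of 9 positive, adjusted p = 0.0191) had 0 called, with Cd79b at 0.37. The adjusted p with an estimated correlation was 0.824 for oxidative phosphorylation and 0.822 for the other lists. The oxidation and oxidative phosphorylation calls were lost without HFD replicate 1 (-0.05 and 0.02) and without HFD+As replicate 2 (-0.06 and 0.03), the xenobiotic call without HFD+As replicate 2 (-0.08; the median was -0.04 without HFD replicate 2), and the lymphocyte call without HFD replicate 2 (0.01), without HFD+As replicate 1 (-0.08) and with the span trend removed (adjusted p = 0.273). Without HFD replicate 1, Cyp4a31 (0.96), Cyp4a14 (0.80), Cyp4a10 (0.69), Nr1i3 (0.73) and Sdha (-0.35) were not called, nor were they without HFD+As replicate 2. Cyp4a31 (1.31), Cyp4a10 (0.89), Nr1i3 (0.83) and Sdha (-0.31) were not called with the span trend removed either, the first 3 at larger changes than before. The medians of oxidation, xenobiotic and oxidative phosphorylation genes were then 0.08, 0.13 and 0.11.

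Between the diets with arsenite, the 10 largest rises among named genes were all of small RNA genes. Against LFD+As, Snord57 rose by 2.21 (SE 0.24, adjusted p = 0.00207, n = 2 pools per group), Snord118 by 2.06 (SE 0.31, adjusted p = 0.00736) and the vault RNA gene Vaultrc5 by 1.70 (SE 0.23, adjusted p = 0.00573). Rnu12 (1.25), Snora74a (1.24), Snora69 (1.22), Snora31 (1.17), Snord49b (1.13), Snord35a (1.13) and Rprl2 (1.10) followed. Chrna4 fell by 1.94 (SE 0.23, adjusted p = 0.00207), Raet1d by 1.85, Ppard by 1.64 (SE 0.20, adjusted p = 0.00207), Cyp26a1 by 1.63 (SE 0.26, adjusted p = 0.00981), Acacb by 1.25 (SE 0.20, adjusted p = 0.00954) and Scd1 by 0.84 (SE 0.13, adjusted p = 0.00736). The kinase gene Pdk4 (-1.26), Camk1d (-1.24), the repressor gene Bcl6 (-1.19), the ammonium transporter gene Rhbg (-1.19), Acss2 (-1.09) and Sqle (-0.43) were lower. Values that did not pass were 0.82 for Nqo1, 0.94 for Mt1, 0.24 for Hmox1, -0.34 for As3mt, -0.12 for Cyp7a1 and 0.01 for Cidec. Without LFD+As replicate 2 Cyp26a1 stood at -1.06, and without HFD+As replicate 2 Bcl6 (-0.69), Rnu12 (0.67), Snora31 (0.53), Snora69 (0.43) and Snord49b (0.75) were among those that lost their calls, while Snord35a lost its call without HFD+As replicate 1 (0.67). Without LFD+As replicate 2 the calls of Snord49b (1.04), Scd1 (-0.69), Acacb (-0.86), Lpin1 (-0.27) and Prodh (-0.32) were among those lost, and 11 of the 60 named calls held, against 35 without LFD+As replicate 1, 16 and 32 without HFD+As replicates 1 and 2, and 44 without either LFD array. Camk1d, Chrna4, Ppard, Raet1d, Rhbg, Rprl2, Snora74a, Snord118 and Snord57 stayed called without any 1 array. Removal of the span trend left 10 of the 60 named calls, those of Camk1d, Chrna4, Cyp26a1, Insig1, Ppard, Raet1d, Rhbg, Scd1, Snord57 and Vaultrc5. The 50 lost kept their sign, 45 with a smaller and 5 with a larger change (median 0.768 times that before). Of the small RNA genes given, Snord118 (1.76, SE 0.35 against 0.31), Snora74a (0.96) and Rprl2 (0.84) then had adjusted p = 0.0508, and Rnu12 (0.95), Snora69 (0.91), Snora31 (0.86), Snord35a (0.79) and Snord49b (0.78) were not called either. The highest unadjusted p that passed went from 0.00512 to 0.000258, and 25 of the 50 lay under the former.

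This comparison had 1227 genes called, 218 higher and 1009 lower, and 3367 at an unadjusted p under 0.05. In the 20% with the shortest spans 156 genes were higher and 38 lower, in the longest 0 and 475, and with the span trend removed 63 were called, 28 higher and 35 lower. Centring each array on its median gave 214, 67 higher and 147 lower. The number was 471 without LFD+As replicate 1, 17 (8 higher, 9 lower) without LFD+As replicate 2 and 31 (20 and 11) without HFD+As replicate 1. Across the 38 small nucleolar RNA genes tested the median was 0.77, and across 58 ribosomal protein genes it was 0.35, both groups of short genes picked after the values were seen.

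Lists of lipid synthesis were lower in HFD+As against LFD+As too. All 20 fatty acid synthesis genes were negative (median -0.67, adjusted p = 8.72e-08), with 12 called and 15 adjusted over the list alone, and the median was -0.43 without LFD+As replicate 2. All 19 cholesterol genes were negative (median -0.30, adjusted p = 0.0102), with Insig1 (-0.55) among 3 called and 6 adjusted over the list alone, and the call was lost without LFD+As replicate 1 (-0.29). Endothelial markers had 16 of 17 negative (median -0.43, adjusted p = 0.00934), with 7 called, such as Stab2 (-0.77), and 9 adjusted over the list alone. Genes of amino acid catabolism had 21 of 23 negative (median -0.24, adjusted p = 0.0225), with Gpt2 (-0.59) and Hal (-0.59) among 5 called and 9 adjusted over the list alone, and lost the call without LFD+As replicate 2 (-0.23) and HFD+As replicate 1 (-0.18). Oxidative phosphorylation genes had 23 of 32 positive (median 0.10, adjusted p = 0.000805), with Ndufb8 (0.54) called higher and Sdha (-0.50) lower, also adjusted over the list alone. Lymphocyte markers (6 of 9 positive, median 0.13, adjusted p = 0.0385) had 0 called and lost the call without LFD+As replicate 1 (0.14), without HFD+As replicate 1 (0.0016) and with the span trend removed (adjusted p = 0.505). The adjusted p with an estimated correlation was 0.824 for the endothelial list, 0.833 for amino acid catabolism and 0.822 for the other 4. Without LFD+As replicate 2, Insig1 (-0.55), Stab2 (-0.64), Gpt2 (-0.60), Hal (-0.47), Ndufb8 (0.61) and Sdha (-0.45) were not called, nor were they without HFD+As replicate 1. After removal of the span trend 2 synthesis genes and 1 cholesterol gene were called lower and 0 endothelial, amino acid and oxidative phosphorylation genes by limma, while these 5 lists stayed called (medians -0.54, -0.23, -0.24, -0.18 and 0.14).

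Whether the diet changed the effect of arsenite was tested as an interaction, and 0 genes passed with limma, with the smallest adjusted p at 0.0591 and 1659 genes at an unadjusted p under 0.05. Lcn2 had the interaction value -3.22 (SE 0.52, adjusted p = 0.0591), the lipopolysaccharide binding protein gene Lbp -1.54 (adjusted p = 0.0635), and Ppard -1.78, Atp11a -1.43, Chrm3 -1.38, the bile acid transporter gene Slc10a2 -1.34 and Lrg1 -1.27 (adjusted p = 0.0591 each). Socs2 had 1.30 (adjusted p = 0.117), Clec2h 1.39, Akr1c19 1.03, Phlda1 0.83 and Gpcpd1 0.77. Scd1 had -0.81 (adjusted p = 0.149), Elovl5 -1.04 (adjusted p = 0.117), Nqo1 1.25 (adjusted p = 0.264), Sqle -0.55, Mt1 -1.53, Hmox1 -0.37, As3mt -0.47, Cyp7a1 0.28 and Cidec -0.26. No single gene therefore passed as differing between the diets in its response to arsenite. This does not show equal responses, as only 18% of simulated interactions of 0.5 log2 units were recovered. Larger differences are not excluded either, as values such as -3.22 for Lcn2 and -1.78 for Ppard did not pass. Leaving out 1 array gave 5 genes without LFD replicate 2, 11 and 23 without LFD+As replicates 1 and 2, 4 and 17 without HFD replicates 1 and 2, 2 and 7 without HFD+As replicates 1 and 2, and 0 without LFD replicate 1 (2308 at an unadjusted p under 0.05).

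Of the lists, 9 were called for the interaction, with 0 members called over all genes. Fatty acid synthesis had 19 of 20 negative (median -0.56, adjusted p = 3.29e-06, 9 lower adjusted over the list alone) and acute phase 21 of 23 (median -0.56, mean -1.02, adjusted p = 4.53e-09, 14 lower adjusted over the list alone). Medians were -0.41 for stress response genes (adjusted p = 0.00292, 3 lower adjusted over the list alone, Creld2 at -0.78), -0.36 for fasting genes (adjusted p = 0.00985, 3 lower, Igfbp1 at -1.40) and -0.22 for cholesterol genes (adjusted p = 0.049). They were 0.02 for NRF2 genes (adjusted p = 0.00301), 0.10 for xenobiotic genes (adjusted p = 0.00221), 0.22 for lymphocyte markers (adjusted p = 0.00299) and 0.11 for pancreas markers (adjusted p = 0.0133). The all-gene median of the interaction was -0.12, and camera tests each list against the other genes. The NRF2 call thus need not mean that the arsenite effect on these genes differed between the diets. With an estimated correlation the adjusted p was 0.824 for cholesterol and 0.822 for the other 8. The stress response and fasting calls were lost without LFD replicate 1 (-0.40 and -0.39), and their medians were -0.27 and -0.23 without HFD+As replicate 1. Lost too were the NRF2 call without HFD+As replicate 2 (-0.07, and medians of -0.04 without LFD replicate 1 and -0.07 without LFD+As replicate 1), the xenobiotic call without LFD+As replicate 1 (0.11) and HFD+As replicate 2 (0.03, and a median of 0.04 without HFD replicate 2), the lymphocyte call without HFD+As replicate 1 (0.05, and a median of 0.0028 without HFD replicate 2), and the pancreas call without LFD replicate 2 (0.02), LFD+As replicate 2 (0.11) and HFD replicate 1 (0.05). The cholesterol call held only without LFD+As replicate 2 (-0.35) or HFD replicate 1 (-0.32). Synthesis and acute phase kept their calls without any 1 array. The pancreas call was also lost with the span trend removed (0.18, adjusted p = 0.0663), and the medians of cholesterol, NRF2, xenobiotic and fasting genes were then -0.10, 0.16, 0.24 and -0.20, with their calls kept.

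Lists called in 0 of the 6 comparisons by camera were lipid droplet and lipid storage (19 genes, median -0.07 in HFD+As against LFD), circadian clock (14 genes, -0.09), p53 targets (21 genes, -0.07) and stellate cell genes (18 genes, -0.20). Members called in HFD+As against LFD were Lpin1 (-0.96) and G0s2 (0.72) of lipid storage, Nr1d1 (-0.98) and Usp2 (0.65) of the clock, Fas (0.54) and Rps27l (0.52) of the p53 targets, and Reln (-0.53) and Sparc (-0.48) of the stellate genes. Each of these 8 calls was lost without at least 1 of the LFD and HFD+As arrays, and the left-out value nearest to 0 was -0.84 for Lpin1, 0.71 for G0s2, -0.81 for Nr1d1, 0.48 for Usp2, 0.43 for Fas, 0.46 for Rps27l, -0.30 for Reln and -0.39 for Sparc. With the span trend removed the calls of Reln (-0.21, adjusted p = 0.404), Sparc (-0.35, adjusted p = 0.0761), Nr1d1 (-0.97, adjusted p = 0.0639) and G0s2 (0.58, adjusted p = 0.054) were lost, and the other 4 held. Lists with too few measured genes to test were neutrophil markers (4 genes, median 0.12, S100a9 called at 0.81), erythroid markers (4 genes, -0.29), adipocyte markers (3 genes, -0.38) and cholangiocyte markers (2 genes, -0.23). Without LFD replicate 1 or HFD+As replicate 1, S100a9 was not called, and with any 1 array left out it lay between 0.65 and 0.96.

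The 3 effects against LFD shared called genes, and shared controls alone also gave shared genes in simulations. LFD+As and HFD shared 3 genes higher and 2 lower (0.0103 and 0.00585 expected for unrelated lists), LFD+As and HFD+As shared 3 and 5 (0.108 and 0.618 expected), and HFD and HFD+As shared 20 and 10 (1.47 and 1.73 expected), with 0 genes called in opposite directions. In simulations of unchanged groups with the same control arrays, lists of the same lengths, taken by smallest p, shared means of 1.08 and 1.11, 1.89 and 3.76, and 17.7 and 9.75 genes, and at most 3 and 4, 3 and 5, and 27 and 13. At the threshold the mean overlap there was 0.19, 0.16 and 0.18 genes, which is low because almost no gene was called. The numbers shared by HFD and HFD+As lay near the simulated means for lists of the same lengths. With only 3 genes higher and 5 lower called in LFD+As, its overlaps can hardly exceed the highest simulated ones, so those decide nothing. Across genes, the fold changes of HFD and HFD+As correlated at r = 0.629 against 0.4995 in the simulations, those of LFD+As and HFD at 0.638 against 0.498, and those of LFD+As and HFD+As at 0.466 against 0.50. Their covariances were 0.0381 against 0.00908, 0.0193 against 0.00906 and 0.0205 against 0.00909, each above the simulated value, by 0.0291, 0.0102 and 0.0114. The simulations held no trend of arrays with gene span. The 2 LFD arrays were not divided between the comparisons, so part of these correlations comes from the shared controls.

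Averaged over both diets, arsenite gave 68 genes, 15 higher and 53 lower, and the diet averaged over both waters gave 915, 357 higher and 558 lower, each with 4 arrays against 4. The genes given here were picked after their values were seen. With arsenite, Socs2 fell by 1.39 (SE 0.13, adjusted p = 0.000854), Chrna4 by 1.43 (SE 0.16, adjusted p = 0.00367), Acly by 0.84 and the fatty acid synthase gene Fasn by 0.76, while Fabp2 rose by 0.72 (SE 0.10, adjusted p = 0.00925), Retsat by 0.72 (SE 0.10, adjusted p = 0.0103), Hspb1 by 0.92 (SE 0.14, adjusted p = 0.0146) and Akr1c19 by 0.79 (SE 0.12, adjusted p = 0.0158). With the high-fat diet, Cyp26a1 fell by 1.95 (SE 0.18, adjusted p = 0.0004) and Raet1d by 1.74 (SE 0.15, adjusted p = 0.000376), and Mt2 rose by 1.86 (SE 0.34, adjusted p = 0.0122). With the span trend removed the arsenite average gave 16 genes, 9 higher and 7 lower, and with quantile normalization 15, 6 and 9. Centring each array gave 337 genes for the diet, 205 higher and 132 lower. Leaving out LFD replicate 1 left 1 gene for arsenite, LFD replicate 2 left 12, LFD+As replicates 1 and 2 left 30 and 145, HFD replicates left 28 and 117, and HFD+As replicates 19 and 35. For the diet the numbers in that order were 366 (264 higher), 94 (29 higher), 711, 147 (74 higher), 1496, 87 (40 higher), 122 (65 higher) and 1080.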

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

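The list calls by camera, with an estimated correlation and without single arrays too, and the 2 counts over other splits of the arrays were planned, while the other tests in this part, and the use of these values to weigh patterns, were chosen only after the results were seen. More genes were lower than higher in HFD+As against LFD (1479 against 430). A trend with gene span that differs between arrays accounts for much of the split, since only 25.9% of the called genes among the 20% of genes with the shortest spans were lower, against 98.8% in the 20% with the longest. A shift of whole arrays moves all spans alike. As the only cause it was argued against by the difference of -0.274 between the medians of the longest and the shortest genes. A shift beside the trend is not excluded by this, and centring each array on its median also lowered the number of genes called. RNA or array handling that differed between pools could give such a trend, and the pools of HFD differed from each other by a span trend of rho -0.275 across genes without any difference in treatment. A change of transcription that favours short genes in HFD+As was not tested and stays open, as both HFD+As arrays carry the trend and RNA quality was not analysed here.

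The acute phase list was called higher with either treatment (1 and 5 of 23 members called in LFD+As and HFD), and its interaction median was -0.56, less than additive, with adjusted p = 0.822 for each with an estimated correlation. A ceiling of the array signal was argued against by the list being lower in HFD+As than in HFD, at a median of -0.31, since a ceiling holds values level, although that call was lost without HFD replicate 2 (-0.22) or HFD+As replicate 1 (-0.21), and the median was -0.20 with the span trend removed. The trend with gene span left the interaction at -0.515 when it was removed. A single pool that stands apart did not carry it either, as the value nearest to 0 with any 1 array left out was -0.464. A weaker acute phase response to both treatments together is therefore a hypothesis, found and tested on the same arrays. Macrophage markers were lower beside it in HFD+As against HFD (median -0.39, 19 of 22 negative, 4 called, and adjusted p = 0.833 with an estimated correlation). With the span trend removed the macrophage median was -0.25 and 0 of these markers were called. A change in cell types thus stays open.

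Fatty acid synthesis genes were lower in HFD+As than in HFD (median -0.81) and LFD (-0.82), each with adjusted p = 0.822 with an estimated correlation. The trend with gene span was argued against by a median of -0.625 in HFD+As against HFD after its removal, although 4 and not 14 of the 20 genes were then called. Feeding state at collection could lower these genes, and the 14 genes known to rise on fasting had a median of -0.229, with Cyp4a10 and Cyp4a14 higher and Igfbp1 lower. A fasted group needs these genes to rise together, and they went both ways, so feeding state cannot be told apart from an effect of arsenite here. Food intake was not given in the labels, and endothelial (median -0.43, 17 of 17 negative) and macrophage markers (-0.39, 19 of 22) were also lower than in HFD (-0.24 and -0.25 with the span trend removed), with adjusted p = 0.824 and 0.833 with an estimated correlation, so a change in cell types stays open too.

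The 8 arrays were split into 4 and 4 in 35 ways, each fitted as 2 groups. As many genes as the real split by diet came from 2 of these, the real one with 7 genes and another with 11. That other split set both LFD arrays, LFD+As replicate 2 and HFD replicate 1 against the rest. It thus kept both LFD arrays against both HFD+As arrays, which differ in treatment. A fit as 2 groups also leaves effects of arsenite in the spread. The count therefore cannot decide on chance for the diet, which was not excluded. For arsenite the real split gave 0 genes with limma (684 at an unadjusted p under 0.05) and the highest other gave 11, and since all 35 splits match a count of 0 whatever the data hold, this count says nothing about chance.

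Camera also gave differences between the diets in the effect of arsenite for other lists. The medians of the interaction were -0.22 for cholesterol biosynthesis, 0.0221 for NRF2 targets, -0.41 for the unfolded protein and stress response, 0.10 for xenobiotic metabolism and -0.36 for gluconeogenesis and fasting. They were 0.22 for lymphocyte markers and 0.11 for exocrine pancreas markers, beside -0.56 each for fatty acid synthesis and the acute phase. All 9 lost their call with an estimated correlation, at adjusted p = 0.822 to 0.824, only synthesis and acute phase kept it without any 1 array, and with the span trend removed the pancreas call was lost (adjusted p = 0.0663) and the cholesterol, NRF2, xenobiotic and fasting medians were -0.10, 0.16, 0.24 and -0.20. Transcript clusters without 1 gene name were not analysed, yet 436 of 6692 tested were called in HFD+As against LFD (293 higher, 143 lower) and 19 in HFD+As against LFD+As (11 higher, 8 lower).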

How the results depend on the processing

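The tests here were planned, except removal of the trend with gene span and the block with crossed numbers in LFD+As, which were chosen only after the data were seen. Over all settings, 1013 of 1238 list results were the same, 222 lost their call and 3 turned, and of 7802 values of named genes 6329 were the same, 1258 lost their call, 191 gained one and 24 turned. Being the same meant only an unchanged direction and an unchanged call or lack of one, whatever the size of the change. Values of genes not called with all arrays are included, as are left-out arrays outside the comparison. The share that stayed the same is therefore no measure of how stable the called genes were. Apart from the lost calls for which a change of SE or of the adjustment was given above, why settings gave different values is open, as the cause was not tested. The pseudocount had no use on log2 values, and a fit to only the arrays compared cannot be made for the interaction and the averages. Array signal limits small changes near background and large ones near saturation.

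Leaving out each array in turn gave 0 to 26 genes for LFD+As against LFD (8 with all arrays), 0 to 72 for HFD (55), 206 to 2050 for HFD+As (1909), 24 to 1121 for HFD+As against HFD (434), 17 to 1481 for HFD+As against LFD+As (1227), 0 to 23 for the interaction (0 by limma, 1659 at an unadjusted p under 0.05), 87 to 1496 for the diet average (915) and 1 to 145 for the arsenite average (68). The lists called ranged over 8 to 12, 9 to 15, 8 to 11, 7 to 13, 6 to 8 and 6 to 13 in the first 6 of these comparisons.

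With no filter on dim genes the counts were 1 for LFD+As, 13 for HFD, 1084 for HFD+As against LFD, 29 for HFD+As against HFD, 165 for HFD+As against LFD+As, 172 for the diet average and 8 for the arsenite average. The stricter filter gave 6 for the interaction, and all probe sets tested singly gave 5 for LFD+As. Quantile normalization gave 5 for LFD+As, 104 for HFD+As against HFD and 15 for the arsenite average, and 6 lists for HFD+As against HFD. Each array centred on its median gave 5 for LFD+As (2 higher, 3 lower), 1013 for HFD+As against LFD (289 and 724), 125 for HFD+As against HFD, 214 for HFD+As against LFD+As, 337 for the diet average and 32 for the arsenite average. With the span trend removed the counts were 1135 for HFD+As against LFD, 43 for HFD+As against HFD, 63 for HFD+As against LFD+As and 16 for the arsenite average, and the all-gene median of HFD+As against HFD moved from -0.13 to 0.0009. Variances with a trend and robust estimation gave 751 for HFD+As against HFD, 17 for the interaction and 128 for the arsenite average. Array weights gave 22 for HFD, 1118 for HFD+As against LFD, 49 for HFD+As against HFD and 33 for the arsenite average. Only the arrays compared gave 18 for LFD+As.

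An adjusted p under 0.1 gave 15 for LFD+As, 97 for HFD, 1577 for HFD+As against HFD, 2231 for HFD+As against LFD+As, 10 for the interaction, 1731 for the diet average and 169 for the arsenite average. An adjusted p with at least 1.5-fold gave 753 for HFD+As against LFD, 245 against HFD, 449 against LFD+As, 112 for the diet average and 35 for the arsenite average. An unadjusted p with at least 1.5-fold gave 55 for LFD+As, 134 for HFD, 774 for HFD+As against LFD, 484 against LFD+As, 466 for the interaction and 122 for the diet average. Camera with an estimated correlation called 0 lists in each of the 6 comparisons, with unadjusted p under 0.05 for 3 lists in LFD+As and 1 in HFD, and fry called 0 as well, with the lowest adjusted p at 0.355.

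As a block, the replicate number gave 230 genes for HFD+As against HFD and changed the call of 1 of 57 called lists. Differences between replicates correlated across genes at r from -0.217 to 0.179 between groups, so the numbers do not pair the arrays. With crossed numbers in LFD+As the block gave 18 genes for LFD+As, 91 for HFD, 944 for HFD+As against HFD, 21 for the interaction and 178 for the arsenite average. Crossing turns the correlations of the LFD+As differences with those of LFD (-0.212) and HFD (-0.217) positive. The block then takes up spread seen in these same data, so more calls could follow from that alone.

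The sign turned in 24 values of named genes, none of which was called with all arrays. With each array left out in turn, values in LFD+As ranged from -0.23 (without LFD+As replicate 1) to 0.42 for Cyp7a1, from -0.21 (without LFD replicate 2; -0.09 without LFD+As replicate 1) to 0.41 for Nqo1, and from -0.078 (without LFD replicate 2; -0.07 without LFD+As replicate 1) to 0.15 for Sqle, which was -0.0038 with quantile normalization. In HFD, As3mt ranged from -0.006 (without HFD replicate 2) to 0.28, and Scd1 was 0.020 with centring. In HFD+As against LFD, As3mt ranged from -0.38 to 0.056 and Cyp7a1 from -0.18 to 0.12 (the upper ends without HFD+As replicate 1), and Cyp7a1 was 0.0078 with the span trend removed. In HFD+As against HFD, Cidec ranged from -0.10 (without HFD+As replicate 2) to 0.32 and Mt1 from -0.39 to 0.17 (without HFD+As replicate 2; 0.12 without HFD replicate 1). There Hmox1 was 0.17 without HFD replicate 1, 0.02 without HFD+As replicate 2, 0.11 with quantile normalization and 0.041 with the span trend removed. In HFD+As against LFD+As, Cidec ranged from -0.23 (without LFD+As replicate 2; -0.20 without HFD+As replicate 2) to 0.25, and Cyp7a1 from -0.45 to 0.20 (without LFD+As replicate 1; 0.03 without HFD+As replicate 1). For the interaction Cyp7a1 ranged from -0.045 (without LFD+As replicate 2; -0.02 without HFD replicate 1) to 0.60. The test of cell cycle genes in LFD+As turned at a median of 0.0324 with the stricter filter and of 0.0327 without LFD+As replicate 2, the lower end of a range to 0.22, and that of fatty acid oxidation genes in HFD+As against HFD turned at -0.023 with fry.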

Other observations

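The tests in this part, and the genes it names, were chosen only after the values were seen. Stat5b, Cish and Ghr, 3 genes of growth hormone signalling, were lower in HFD+As than in LFD, without a test of the pathway as a group. Stat5b, the gene of the main transcription factor of the pathway, fell by 0.75 (SE 0.15, adjusted p = 0.00917, n = 2 pools of 5 mice per group), Cish, a target that feeds back on the receptor, by 1.03 (SE 0.25, adjusted p = 0.0182) and the receptor gene Ghr by 0.41 (SE 0.12, adjusted p = 0.0362). Without LFD replicate 1 these calls were lost (-0.69, -0.95 and -0.42), as they were without HFD+As replicate 1 (-0.82, -0.54 and -0.39). Cish and Ghr were also not called without LFD replicate 2 (-1.11 and -0.40), nor was Ghr without HFD+As replicate 2 (-0.43) or either LFD+As array (-0.41). Ghr stood at -0.11 with the span trend removed and was not called. In LFD+As, Cish stood at -1.29 (SE 0.25, adjusted p = 0.149) and Bcl6, a repressor that competes with STAT5, at 1.28 (adjusted p = 0.165), and both passed without either HFD+As array at the same values.

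Of genes of retinoid handling, 5 besides Cyp26a1 were picked in HFD+As against LFD, and no retinoid list was tested. The retinol dehydrogenase gene Rdh11 fell by 1.02 (SE 0.16, adjusted p = 0.00334), the reductase gene Dhrs3 by 0.57 (SE 0.14, adjusted p = 0.0174) and the receptor gene Rarb by 0.65 (SE 0.16, adjusted p = 0.0174), beside the fall of Cyp26a1. Retsat, which saturates retinol, rose by 0.90 (SE 0.14, adjusted p = 0.00381), and like Rdh11 it was called without any 1 array. Dhrs3 and Rarb were not called without LFD replicate 1 (-0.59 and -0.55), LFD replicate 2 (-0.55 and -0.74), HFD+As replicate 1 (-0.62 and -0.68) or HFD+As replicate 2 (-0.51 and -0.62). Rdh16 stood at -0.48 (adjusted p = 0.0428) and lost its call without LFD replicate 1 (-0.40), LFD replicate 2 (-0.56) and HFD+As replicate 1 (-0.35). Rarb (-0.31), Dhrs3 (-0.41) and Rdh16 (-0.40) were not called with the span trend removed.

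As a hypothesis, weaker growth hormone signalling could lie behind the fall of Socs2 with arsenite. The 6 other targets tested were all negative in LFD+As, with a median of -0.449, but none was called. They were also mostly negative with the diet alone (5 of 6 in HFD, median -0.33), split for arsenite on the high-fat diet (4 negative and 2 positive, median -0.22) and had an interaction median of 0.41, with 6 of 6 positive. In HFD+As against LFD all 6 were negative (median -0.33), with Onecut1 and Cish called. The low values are thus not particular to arsenite, and the data leave the hypothesis open. Phosphorylated STAT5 in livers of single mice, taken at set times after a growth hormone pulse, would test it.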
